A study of Mus musculus with 18 samples.

How the data were processed

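RNA was measured in 18 mouse melanoma allografts, 6 each treated with vehicle, with the MEK inhibitor AZD6244 or by doxycycline withdrawal. The tumours are distinct and count as biological replicates under the series design. Per the submitters' protocol a piece of about 50 mg, trimmed of skin, was kept in RNAlater, total RNA was extracted with Trizol, and 10 ug were labelled with biotin for one-colour Affymetrix arrays. The deposited table holds 45037 probe sets and 18 arrays of probe set intensity values, which the authors had summarised and brought to a common scale. Their processing notes name MAS5 and RMA without versions and without saying which made this table. The values were read as linear intensities because all were positive and array medians lay between 72.3 and 78.5. If they were made by another transformation, fold changes would be on another scale. No labels give a batch or date, so none could be tested. The number of arrays limits the precision.

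Probe sets were assigned to genes by the platform annotation, with symbols updated from a mouse gene table. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had no entry. The symbols covered 18193 genes, and 9010 of these had several probe sets. Each gene was represented by its probe set with the highest mean. Values were transformed to log2(intensity + 16), and genes with a mean at or below the 25th percentile of all probe sets (log2 value 5.305, intensity 23.5) were left out, leaving 15005. No genome coordinates were used.

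The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with 15 residual degrees of freedom per gene and an estimated prior of 3.46. The contrasts were NRAS-off minus vehicle, MEK inhibitor minus vehicle and NRAS-off minus MEK inhibitor, with Benjamini-Hochberg adjusted p under 0.05 within each contrast. A gene changed further by an arm when it passed against vehicle and against the other arm in the matching direction. Because both contrasts against vehicle share its arrays, their correlation and overlap were compared with 100 or 20 simulated draws of unchanged arms and with the 20 ways of splitting the vehicle tumours 3 and 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

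Before the data were examined, 23 gene lists and 14 cell type marker lists were fixed. The gene lists cover MAPK output, immediate early genes, G1/S, G2/M, G1 regulators, the BCL2 family, p53 targets, FOXO targets, receptor tyrosine kinases, pigmentation, neural crest genes, type I interferon response, antigen presentation, cytokines, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, ATF4 and the unfolded protein response, lysosome and autophagy, WNT targets, and extracellular matrix. The marker lists cover melanocytic cells, fibroblasts, smooth muscle and pericytes, endothelial cells, macrophages, neutrophils, dendritic cells, NK and lymphoid cells, mast cells, keratinocytes, adipocytes, skeletal muscle, Schwann cells and red blood cells. The red blood cell list had fewer than 5 tested members and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 108 tests of the 3 contrasts. Camera compares a list with the other genes, and a list is called shifted when its adjusted p was under 0.05. Counts of members were given over all genes and adjusted over the list alone.

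Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and falls per contrast among changed genes whose groups do not overlap, up to 4 members of each list with the largest change, and a set of pathway genes always shown.

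The fit was checked on simulated data with known changes. It recovered 88.1%, 95.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 false calls among the unchanged genes of the 15005 fitted. Camera recovered a list shifted by 0.3 in both contrasts that use the shifted arm and called 0 lists that share no gene with it. The simulated genes were drawn independently, so this does not test false list calls where genes are correlated.

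Alternatives were no filter, a filter at the 50th percentile, the mean of all or the most variable probe set per gene, median centring, quantile normalization, pseudocounts of 1 and 64, a trended robust prior, array weights, only the 2 groups compared, a replicate block, a 2-fold threshold, an adjusted p under 0.01, macrophage and fibroblast scores as covariates, camera with an estimated correlation, fry, and leaving out each tumour. With the replicate block 4701 genes rose and 4027 fell in NRAS-off minus vehicle. After seeing the data, leaving out both tumours with the most keratinocyte transcript, and keratinocyte and muscle scores as covariates, were added.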

Results

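Gene expression was profiled in 18 mouse melanoma allografts. The tumours grew from iNRAS-475, a mouse melanoma cell line in which doxycycline keeps an NRAS oncogene switched on. Cells were injected into the skin of nude mice, which lack mature T cells, and the mice drank water with 2 mg/ml doxycycline. After 6 weeks, at tumour volumes of 200 to 500 mm3, the mice entered 1 of 3 arms with 6 distinct tumours each. One arm received vehicle. The MEK inhibitor arm received 100 mg/kg AZD6244 (selumetinib, an allosteric inhibitor of the kinases MEK1 and MEK2) for 4 days. In the NRAS-off arm doxycycline was withdrawn for 4 days. Each tumour was read on 1 one-colour Affymetrix array, and the number of arrays, not a read depth, limits the precision.

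The arrays separated by arm. Array medians lay between 72.3 and 78.5 intensity units, and pairs of tumours of the same arm correlated at 0.9871 to 0.997 on the log2 scale. The first principal component held 57.4% of the variance and the second 19.9%. Of 15005 genes tested, 8899 (59.3%) changed between NRAS-off and vehicle tumours, 6787 (45.2%) between MEK inhibitor and vehicle tumours, and 7052 (47.0%) between the 2 treated arms. Values below are log2 changes ± SE on the log2(intensity + 16) scale with 6 tumours per arm, and adjusted p values come from limma.

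The mouse Nras gene was examined first. Its 3 probe sets fell by 0.19, 0.43 and 0.28 in the NRAS-off tumours and by 0.27, 0.31 and 0.23 in the MEK inhibitor tumours. Between the treated arms they did not pass the threshold (limma adjusted p = 0.332, 0.213 and 0.458). The labels do not say whether these probe sets read the inducible transgene, so they do not check whether it was switched off.

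The comparison of NRAS-off with vehicle tumours asks which transcripts change when doxycycline, and with it the oncogene, is withdrawn. Only this arm had doxycycline withdrawn, so an effect of doxycycline itself cannot be told apart from loss of the oncogene. Transcripts controlled by the MAPK pathway, the kinase cascade below RAS, fell together: 25 of 27 tested members of the MAPK output list fell, none rose, and the median change was −2.59. Dusp6, a phosphatase that acts on ERK, went from an intensity of 8325 ± 564 (SD, n = 6) to 1118 ± 307, a fall of 2.92 ± 0.14. Etv4 and Etv5, transcription factors induced by ERK signalling, fell by 2.93 ± 0.11 and 2.67 ± 0.14. The feedback inhibitors Spry2 and Spry4 fell by 2.01 ± 0.13 and 3.05 ± 0.15. Fosl1 fell by 3.87 ± 0.15 and Dusp4 fell by 4.57 ± 0.17. The growth factor gene Ereg fell by 5.09 ± 0.31 and the chromatin protein gene Hmga2 fell by 5.52 ± 0.19. Adjusted over the list alone, the count was also 25. The camera adjusted p was 9.02e-17, and adjusted p = 0.183 with an estimated correlation.

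**Figure D1:**
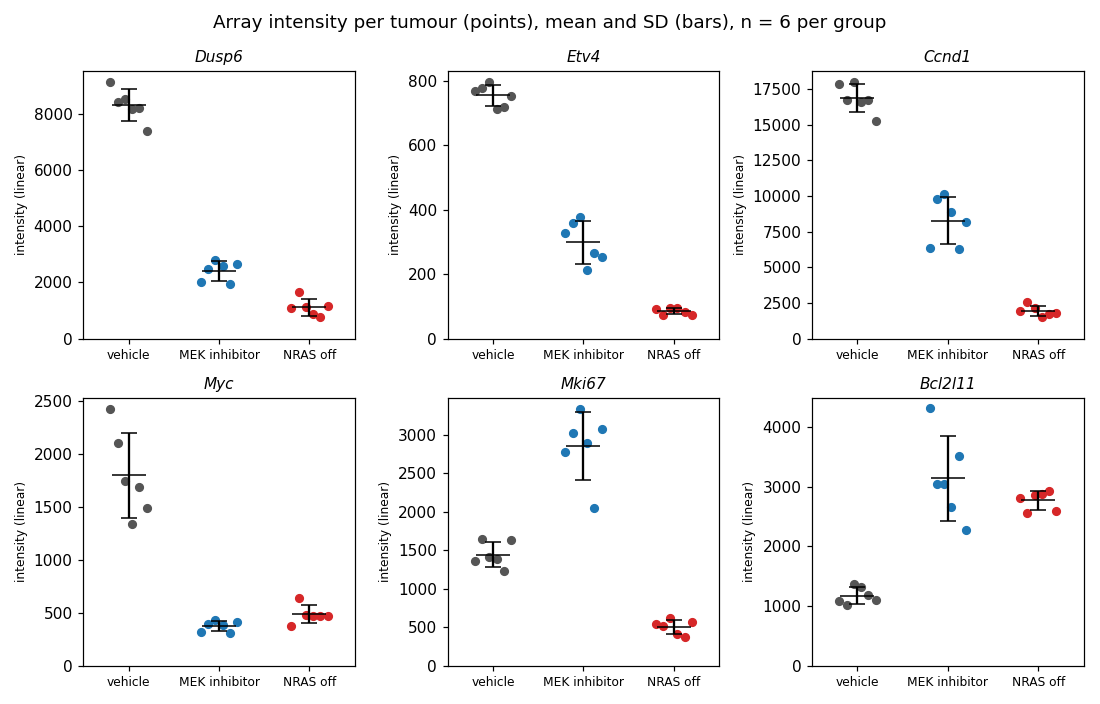
Array intensity on a linear axis for 6 genes in vehicle, MEK inhibitor and NRAS-off tumours. Points are single tumours, and bars show the mean and SD of 6. Ccnd1 averaged 16850 in vehicle, 8257 in MEK inhibitor and 1934 in NRAS-off tumours, while Mki67 averaged 1445, 2855 and 503.

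Cell cycle transcripts fell in the NRAS-off tumours. In the G2/M and mitosis list all 35 tested members fell, with a median of −1.56 (camera adjusted p = 2.35e-17, and adjusted p = 0.34 with an estimated correlation). Bub1, a mitotic checkpoint kinase, fell by 2.32 ± 0.19, Top2a by 2.10 ± 0.15 and the proliferation marker Mki67 by 1.51 ± 0.13. In the G1/S and DNA replication list 30 of 34 fell and none rose, with a median of −0.96 (camera adjusted p = 1.1e-10, and adjusted p = 0.356 with an estimated correlation). Uhrf1 fell by 2.49 ± 0.13 and Rrm2, a subunit of ribonucleotide reductase, by 2.31 ± 0.13. Adjusted over the list alone, the counts were again 35 and 30. Among regulators of G1, Ccnd1, which encodes cyclin D1, fell by 3.13 ± 0.13, its partner kinase gene Cdk4 by 0.22 ± 0.06, Cdkn2b by 1.48 ± 0.08 and Cdkn1b by 0.51 ± 0.09. Cdkn1c, which encodes the CDK inhibitor p57, rose by 3.76 ± 0.19. The G1 regulator list as a whole did not pass in camera (median −0.34, 6 rose and 11 fell of 20, camera adjusted p = 0.0933), although it passed in fry.

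Biosynthetic programs also fell. Myc fell by 1.84 ± 0.13, and of the ribosome biogenesis and MYC target list 25 of 26 members fell, with a median of −0.57 (camera adjusted p = 4.17e-10, and adjusted p = 0.183 with an estimated correlation). Nop58 fell by 1.07 ± 0.09 and Fbl, the nucleolar methyltransferase fibrillarin, by 1.03 ± 0.05. Of 18 cholesterol synthesis genes 17 fell and 1 rose (median −0.67, camera adjusted p = 4.81e-07, and adjusted p = 0.308 with an estimated correlation). Sqle, which encodes squalene epoxidase, fell by 2.43 ± 0.15 and Idi1 by 2.16 ± 0.14. In the list of ATF4 targets and the unfolded protein response 13 of 22 fell and 3 rose (median −0.30, camera adjusted p = 0.00549, and adjusted p = 0.391 with an estimated correlation). The members with the largest falls were the ATF4 targets Asns (3.12 ± 0.09), Chac1 (2.91 ± 0.15) and Trib3 (2.34 ± 0.13).

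Glycolysis and hypoxia genes fell as well. Of 17 glycolysis genes 14 fell and 1 rose (median −0.83, camera adjusted p = 6.8e-05, and adjusted p = 0.358 with an estimated correlation). The glucose transporter gene Slc2a3 fell by 1.80 ± 0.14 and hexokinase gene Hk1 by 1.58 ± 0.07. Of 24 hypoxia genes 12 fell and 4 rose (median −0.49, camera adjusted p = 0.0127, and adjusted p = 0.56 with an estimated correlation). Bhlhe40 fell by 1.51 ± 0.09 and Vegfa by 1.36 ± 0.08. With macrophage and fibroblast marker scores as covariates, the medians of these lists turned to 0.065 and 0.281.

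Transcripts of several immune and stromal cell types rose in the NRAS-off tumours. All 17 tested antigen presentation genes rose, with a median of 1.56 (camera adjusted p = 3.77e-07, and adjusted p = 0.358 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose by 2.30 ± 0.30, the MHC class I transactivator gene Nlrc5 by 2.23 ± 0.32 and H2-Ab1 by 1.93 ± 0.26. Of 24 type I interferon response genes 23 rose (median 1.29, camera adjusted p = 4.33e-08, and adjusted p = 0.358 with an estimated correlation), with Ifit3 up by 2.56 ± 0.17 and Irgm1 by 2.38 ± 0.37. Of 17 macrophage markers 16 rose (median 1.34, camera adjusted p = 4.33e-05, and adjusted p = 0.419 with an estimated correlation), among them Mpeg1 by 1.79 ± 0.12, Aif1 by 1.54 ± 0.20 and Adgre1, which encodes F4/80, by 1.48 ± 0.21. Of 8 dendritic cell markers 7 rose (median 0.65, camera adjusted p = 0.0327, and adjusted p = 0.34 with an estimated correlation), with Itgax up by 1.34 ± 0.27 and Zbtb46 by 1.03 ± 0.12.

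Of 16 fibroblast markers 13 rose and 3 fell (median 1.16, camera adjusted p = 4.56e-05, and adjusted p = 0.308 with an estimated correlation). The matrix genes Lum, Dcn and Postn rose by 2.98 ± 0.10, 2.80 ± 0.12 and 2.40 ± 0.10. Of 15 endothelial markers 13 rose (median 0.78, camera adjusted p = 0.00101, and adjusted p = 0.397 with an estimated correlation). Vwf rose by 1.63 ± 0.15, while Flt1, the VEGF receptor 1 gene on the same list, fell by 3.52 ± 0.16. All 12 skeletal muscle markers rose (median 2.22, camera adjusted p = 0.000172, and adjusted p = 0.43 with an estimated correlation), including Myh1 by 3.35 ± 0.42 and Pvalb by 2.82 ± 0.42. All 5 Schwann cell markers rose (median 1.12, camera adjusted p = 0.0128, and adjusted p = 0.308 with an estimated correlation), with Scn7a up by 2.53 ± 0.21 and Cdh19 by 1.11 ± 0.10. Of 7 adipocyte markers 4 rose (median 0.81, camera adjusted p = 0.0329, and adjusted p = 0.43 with an estimated correlation), with Lpl up by 3.40 ± 0.20 and Fabp4 by 1.92 ± 0.25. The adipocyte call ended without vehicle replicate 6 (median 0.805). Keratinocyte markers were high in a single NRAS-off tumour: replicate 2 had a Krt14 intensity of 6785 against 27.4 to 117 in the other 5 NRAS-off tumours, and none of 11 keratinocyte markers passed the threshold (Krt14 1.58 ± 0.88, limma adjusted p = 0.134, and Krt10 1.12 ± 0.60, adjusted p = 0.115). Without this tumour Krt10 passed at 0.318. Of 21 lysosome and autophagy genes 13 rose and 4 fell (median 0.38, camera adjusted p = 0.0301, and adjusted p = 0.419 with an estimated correlation), with Ctsa up by 0.64 ± 0.07 and Lamp2 by 0.62 ± 0.07.

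Pigment cell and cell death lists did not pass in camera, while single members changed. The mean score of the melanocytic marker list was higher by 0.557 than in vehicle tumours (exact permutation p = 0.00216). Against the other genes the list did not pass (median 0.37, 5 rose and 1 fell of 9, camera adjusted p = 0.178). Within it the melanosome genes Pmel and Mlana rose by 2.30 ± 0.27 and 0.94 ± 0.10 and Mitf, the melanocyte lineage transcription factor, by 0.89 ± 0.07. Of 23 genes of the BCL2 family and apoptosis list 9 rose and 4 fell (median 0.05, camera adjusted p = 0.263). The pro-apoptotic genes Bmf and Bcl2l11, which encodes BIM, rose by 1.90 ± 0.09 and 1.23 ± 0.12, and the anti-apoptotic Bcl2l1 fell by 1.26 ± 0.07. Map2k1, which encodes MEK1, fell by 0.17 ± 0.07 (limma adjusted p = 0.0365). This call ended without any 1 of NRAS-off replicates 1, 4, 5 and 6 or vehicle replicates 1, 2, 4 and 5 (−0.148 to −0.166), and Braf differed by 0.01 ± 0.06 (limma adjusted p = 0.856).

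The 10 genes with the largest falls and no overlap between the arms were Nefl, Nppb, Hmga2, Ereg, Lgr6, Crabp1, Slc14a1, Prkg2, Gzmd and Pcolce2, from −5.96 ± 0.18 for the neurofilament gene Nefl to −4.66 ± 0.29 for Pcolce2. The 10 with the largest rises were Kcna1, Fmod, Ptn, Gpr17, Plagl1, Gbp6, Cilp, C1qtnf3, Col8a2 and Slc40a1, from 5.34 ± 0.15 for the potassium channel gene Kcna1 to 3.81 ± 0.12 for the iron exporter gene Slc40a1. Adjusted over the list alone, 13 hypoxia genes fell, 14 endothelial markers rose, and the counts of the other shifted lists stayed as given. In all, 4772 genes rose and 4127 fell, and in 5868 of these the 12 tumours did not overlap between the arms, which chance gives for 0.216% of genes. With macrophage and fibroblast marker scores as covariates, 157 genes rose and 283 fell. Those scores lay 87.6% and 93.5% between the arms, and the median SE was 3.94 times as large. The endothelial, skeletal muscle and Schwann cell medians turned to −0.315, −0.049 and −0.302, the lysosome and dendritic cell calls ended (0.209 and 0.242), and the keratinocyte list passed (3.135). With keratinocyte and skeletal muscle scores as covariates the hypoxia, endothelial, dendritic, adipocyte and Schwann cell calls ended (−0.003, 0.267, 0.719, 0.808 and 1.4).

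The comparison of MEK inhibitor with vehicle tumours asks what blocking the kinase below RAS and RAF does while the oncogene stays on. MAPK output again fell, with 26 of 27 members down, none up over all genes, and a median of −1.53 (camera adjusted p = 5.74e-18, and adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone, 26 fell and 1 rose. Dusp6 fell by 1.79 ± 0.14, Etv4 by 1.32 ± 0.11, Etv5 by 1.53 ± 0.14, Spry2 by 0.67 ± 0.13, Spry4 by 2.23 ± 0.15 and Fosl1 by 2.23 ± 0.15. Ereg fell by 3.72 ± 0.31, Dusp5 by 2.69 ± 0.17, Dusp4 by 2.63 ± 0.17 and Egr3 by 2.54 ± 0.19. Of 14 immediate early genes 4 fell and 2 rose (median −0.13, camera adjusted p = 0.162). Egr2 fell by 3.27 ± 0.14 and Egr1 by 1.72 ± 0.18, while Atf3 rose by 2.28 ± 0.15.

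The cell cycle lists shifted up under the inhibitor. In the G2/M list 34 of 35 members rose, with a median of 0.61 (camera adjusted p = 1.41e-09, and adjusted p = 0.406 with an estimated correlation). Mki67 rose by 0.97 ± 0.13, Nusap1 by 1.00 ± 0.14, Cenpf by 0.93 ± 0.16 and Ccna2, which encodes cyclin A2, by 0.84 ± 0.13. Of 34 G1/S and replication genes 19 rose and 2 fell, or 21 and 2 when adjusted over the list alone (median 0.32, camera adjusted p = 0.00211, and adjusted p = 0.624 with an estimated correlation). Dscc1 rose by 0.95 ± 0.14, Prim1 by 0.74 ± 0.12 and the DNA ligase gene Lig1 by 0.59 ± 0.08. Ccnd1 fell by 1.05 ± 0.13, Cdkn2b fell by 1.05 ± 0.08 and Cdkn2c rose by 0.91 ± 0.08. Cdk4 differed by 0.04 ± 0.06 and Cdkn1b by −0.11 ± 0.09 (limma adjusted p = 0.605 and 0.34). The G1 regulator list had a median of 0.05 with 7 up and 4 down of 20 (camera adjusted p = 0.888).

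Myc fell by 2.19 ± 0.13, and 22 of 26 ribosome biogenesis and MYC target genes fell (median −0.64, camera adjusted p = 1.46e-13, and adjusted p = 0.183 with an estimated correlation), among them Rrp12 by 0.99 ± 0.08, Srm by 0.92 ± 0.11 and Tsr1 by 0.92 ± 0.06. Of 18 cholesterol synthesis genes 14 fell and none rose (median −0.39, camera adjusted p = 7.37e-06, and adjusted p = 0.308 with an estimated correlation), with Msmo1 down by 1.65 ± 0.12 and Cyp51 by 1.20 ± 0.14. Of 22 ATF4 and unfolded protein response genes 12 fell and 3 rose (median −0.31, camera adjusted p = 0.000394, and adjusted p = 0.34 with an estimated correlation), with Chac1, Trib3 and Asns down by 2.18 ± 0.15, 1.82 ± 0.13 and 1.52 ± 0.09. FOXO target genes rose: 12 of 20 were up and 1 down (median 0.51, camera adjusted p = 0.000172, and adjusted p = 0.224 with an estimated correlation). The ubiquitin ligase gene Fbxo32 rose by 1.56 ± 0.09, Pik3ip1 by 1.40 ± 0.11 and Foxo3 by 1.21 ± 0.10. Bcl2l11, a member of this list too, rose by 1.38 ± 0.12, Bmf rose by 1.75 ± 0.09 and Bcl2l1 fell by 0.48 ± 0.07. Glycolysis (median −0.08, 3 up and 5 down of 17, camera adjusted p = 0.321) and hypoxia genes (median 0.12, 9 up and 4 down of 24, camera adjusted p = 0.575) did not shift as lists, although the stress gene Ddit4 rose by 1.57 ± 0.14 and the lactate transporter gene Slc16a1 fell by 1.09 ± 0.08.

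Macrophage and mast cell markers fell in the MEK inhibitor tumours. Of 17 macrophage markers 13 fell and none rose (median −0.96, camera adjusted p = 0.000308, and adjusted p = 0.457 with an estimated correlation). The mannose receptor gene Mrc1 fell by 1.52 ± 0.28, Cd68 by 1.28 ± 0.26 and C1qa by 1.14 ± 0.24. Of 8 mast cell markers 6 fell (median −0.86, camera adjusted p = 0.00673, and adjusted p = 0.381 with an estimated correlation), with the mast cell protease genes Mcpt1 and Mcpt4 down by 1.97 ± 0.23 and 1.37 ± 0.24. Mcpt1 fell in NRAS-off tumours too, where most markers of this list rose. Of 23 cytokine and chemokine genes 8 fell and none rose (median −0.23, camera adjusted p = 0.0128, and adjusted p = 0.406 with an estimated correlation), with Ccl12 down by 2.14 ± 0.30, Cxcl14 by 2.07 ± 0.18 and Ccl9 by 1.53 ± 0.20. With macrophage and fibroblast scores as covariates the cytokine median turned to 0.383. Antigen presentation did not shift as a list (median −0.18, 2 up and 6 down of 17, camera adjusted p = 0.236), although it passed without MEK inhibitor replicate 5 (median −0.233), and its class II genes H2-Aa and Cd74 fell by 1.16 ± 0.29 and 1.03 ± 0.30. Type I interferon genes had a median of 0.16 with 5 up and none down of 24 (camera adjusted p = 0.315), with Ifit3 and Ifit2 up by 0.84 ± 0.17 and 0.76 ± 0.08. In the dendritic cell list 1 of 8 fell (median −0.17, camera adjusted p = 0.288), which was Itgax (1.02 ± 0.27).

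Of 16 fibroblast markers 9 rose and 2 fell (median 0.55, camera adjusted p = 0.00175, and adjusted p = 0.358 with an estimated correlation), with Postn up by 1.53 ± 0.10 and Col1a1 by 1.40 ± 0.14. All 12 skeletal muscle markers rose here too (median 1.41, camera adjusted p = 0.000426, and adjusted p = 0.457 with an estimated correlation), with Myh1 up by 2.38 ± 0.42 and Tnnc2 by 1.61 ± 0.34. Of 5 Schwann cell markers 3 rose (median 0.84, camera adjusted p = 0.033, and adjusted p = 0.34 with an estimated correlation), with Cdh19 up by 1.22 ± 0.10 and Scn7a by 1.09 ± 0.21. This call ended without MEK inhibitor replicate 4 (median 0.745) and without both NRAS-off replicate 2 and MEK inhibitor replicate 6 (median 0.771). Endothelial markers had a median of 0.08 with 3 up and 2 down of 15 (camera adjusted p = 0.91), and Flt1 fell by 2.67 ± 0.16. None of 11 keratinocyte markers passed the threshold (median 0.14, camera adjusted p = 0.987, Krt14 0.26 ± 0.88). In the adipocyte list 1 of 7, Lpl, rose (0.81 ± 0.20, list median 0.01, camera adjusted p = 0.867). Melanocytic markers had a median of 0.23 with 3 up and 1 down of 9 (camera adjusted p = 0.256), with Pmel and Sox10 up by 0.80 ± 0.27 and 0.50 ± 0.09. The Pmel call ended without MEK inhibitor replicate 6 (0.697). Mitf differed by 0.11 ± 0.07, Braf by 0.04 ± 0.06 and Map2k1 by −0.02 ± 0.07 (limma adjusted p = 0.218, 0.646 and 0.825).

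The largest falls without overlap were those of Nppb, Ereg, Bmp2, Egr2, Mmp1a, Dusp2, Phlda2, S100a3, Ucn2 and Dusp5, from −4.09 ± 0.18 for Nppb to −2.69 ± 0.17 for Dusp5. The largest rises were those of Kcna1, Rcan2, H2al3, Ptn, Efhd1, C1qtnf3, Ntng1, Cdh10, Rgs2 and Penk, from 4.43 ± 0.15 for Kcna1 to 2.76 ± 0.53 for Penk. Adjusted over the list alone, 24 ribosome and MYC target genes and 13 ATF4 and unfolded protein response genes fell, 13 FOXO targets and 10 fibroblast markers rose, and 7 mast cell markers fell. In all 3645 genes rose and 3142 fell, and 3800 of them had no overlap between the arms. With macrophage and fibroblast scores as covariates 533 rose and 703 fell, with a median SE 2.47 times as large. The G1/S, mast cell, skeletal muscle and Schwann cell calls ended (medians 0.267, −0.061, 0.899 and 0.152), and the hypoxia and type I interferon lists passed (0.332 and 0.481). With keratinocyte and skeletal muscle scores as covariates the G1/S and Schwann cell calls ended (0.203 and 0.591).

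**Figure D2:**
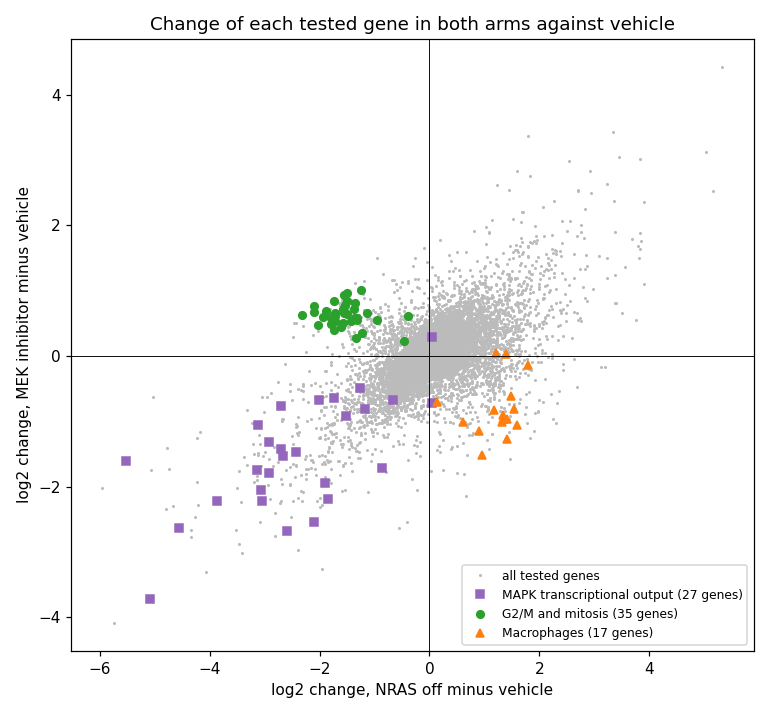
Log2 change of each of 15005 tested genes in NRAS-off minus vehicle tumours (horizontal axis) and in MEK inhibitor minus vehicle tumours (vertical axis). MAPK output genes (27, squares) lie mostly at lower left, G2/M genes (35, circles) at upper left and macrophage markers (17, triangles) mostly at lower right.

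The direct comparison of the 2 treated arms asks where switching off NRAS by doxycycline withdrawal and inhibiting MEK differ. An effect of doxycycline itself cannot be told apart here either. The vehicle arrays do not enter the log2 differences of this comparison but do enter the variance estimate. Fitted with only the 2 treated arms, 6789 of the 7052 calls were kept. All 35 G2/M genes were lower in NRAS-off than in MEK inhibitor tumours, with a median difference of −2.25 (camera adjusted p = 6.61e-30, and adjusted p = 0.255 with an estimated correlation). Top2a differed by −2.86 ± 0.15, Cdca8 by −2.77 ± 0.15 and Mki67 by −2.47 ± 0.13. Of 34 G1/S genes 31 were lower and none higher (median −1.24, camera adjusted p = 8.22e-18, and adjusted p = 0.308 with an estimated correlation), and Rrm2 and Uhrf1 differed by −2.77 ± 0.13 each. Of 20 G1 regulators 13 were lower and 5 higher (median −0.42, camera adjusted p = 0.0105, and adjusted p = 0.308 with an estimated correlation). Ccnd1 differed by −2.08 ± 0.13, Rbl1 by −1.25 ± 0.14, Cdk4 by −0.26 ± 0.06, Cdkn1b by −0.40 ± 0.09 and Cdkn1c by 3.21 ± 0.19.

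MAPK output was lower in the NRAS-off arm, in 19 of 27 genes, and higher in 3 (median −1.03, camera adjusted p = 9.66e-07, and adjusted p = 0.34 with an estimated correlation). Hmga2 differed by −3.91 ± 0.19, Dusp4 by −1.94 ± 0.17, Ier3 by −1.93 ± 0.14, Fosl1 by −1.64 ± 0.15, Etv4 by −1.61 ± 0.11, Spry2 by −1.33 ± 0.13, Etv5 by −1.14 ± 0.14, Dusp6 by −1.13 ± 0.14 and Spry4 by −0.83 ± 0.15. Myc lay the other way, higher by 0.35 ± 0.13 (limma adjusted p = 0.0403). The Myc call ended without any 1 of MEK inhibitor replicates 1, 2, 4 and 5 or NRAS-off replicates 2 to 6 (0.265 to 0.36), and the ribosome biogenesis and MYC target list did not differ as a whole (median −0.10, 6 higher and 9 lower of 26, camera adjusted p = 0.706). Bcl2l11 differed by −0.15 ± 0.12 (limma adjusted p = 0.299), while Bid and Mcl1 were higher by 1.11 ± 0.11 and 0.71 ± 0.07. The BCL2 family list had a median of −0.04 with 7 higher and 5 lower of 23 (camera adjusted p = 0.848). Mitf was higher by 0.78 ± 0.07. Map2k1 differed by −0.15 ± 0.07 and Braf by −0.02 ± 0.06 (limma adjusted p = 0.0802 and 0.77), and Map2k1 passed without NRAS-off replicate 3 (−0.196).

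Antigen presentation, interferon, cytokine, macrophage, dendritic and mast cell lists were higher in the NRAS-off arm. All 17 antigen presentation genes were higher (median 1.87, camera adjusted p = 2.88e-11, and adjusted p = 0.308 with an estimated correlation), with Cd74 at 3.34 ± 0.30, H2-Aa at 3.06 ± 0.29 and H2-Ab1 at 2.80 ± 0.26. Of 17 macrophage markers 16 were higher (median 2.24, camera adjusted p = 2.6e-11, and adjusted p = 0.308 with an estimated correlation), with Cd68 at 2.69 ± 0.26, Ms4a7 at 2.66 ± 0.27 and Mrc1 at 2.48 ± 0.28. Of 24 type I interferon genes 23 were higher and 1 lower (median 1.22, camera adjusted p = 1.04e-08, and adjusted p = 0.356 with an estimated correlation), with Rtp4 at 2.12 ± 0.20 and Ifit1 at 1.81 ± 0.25. Of 23 cytokine and chemokine genes 18 were higher and 1 lower (median 1.22, camera adjusted p = 7.23e-05, and adjusted p = 0.308 with an estimated correlation), with Cxcl9 at 3.16 ± 0.73 and Ccl12 at 2.81 ± 0.30. All 8 dendritic cell markers were higher (median 0.85, camera adjusted p = 0.000864, and adjusted p = 0.224 with an estimated correlation), with Itgax at 2.36 ± 0.27 and Zbtb46 at 1.05 ± 0.12. Of 8 mast cell markers 7 were higher and 1 lower (median 0.97, camera adjusted p = 0.00332, and adjusted p = 0.358 with an estimated correlation), with Cpa3 at 1.87 ± 0.29 and Mcpt4 at 1.54 ± 0.24.

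Fibroblast, endothelial, adipocyte and NK and lymphoid markers were also higher in the NRAS-off arm. Of 16 fibroblast markers 12 were higher (median 0.52, camera adjusted p = 8.98e-05, and adjusted p = 0.308 with an estimated correlation), with Lum at 1.96 ± 0.10 and Dcn at 1.74 ± 0.12. Of 15 endothelial markers 13 were higher and 2 lower (median 0.77, camera adjusted p = 0.000172, and adjusted p = 0.358 with an estimated correlation), with Kdr at 1.26 ± 0.12 and Cldn5 at 1.15 ± 0.12. Of 7 adipocyte markers 4 were higher (median 0.83, camera adjusted p = 0.00779, and adjusted p = 0.358 with an estimated correlation), with Lpl at 2.60 ± 0.20 and Fabp4 at 1.79 ± 0.25. Of 11 NK and lymphoid markers 9 were higher and 2 lower (median 1.07, camera adjusted p = 0.0328, and adjusted p = 0.542 with an estimated correlation), with Cd3g at 1.88 ± 0.41 and Klrd1 at 1.52 ± 0.28. The NK and lymphoid call ended with a pseudocount of 64 (median 0.612). Skeletal muscle and keratinocyte markers, which can mark attached tissue, had medians of 0.78 (3 higher of 12, camera adjusted p = 0.0683) and 0.83 (none of 11 past the threshold, camera adjusted p = 0.315). The muscle list passed without vehicle replicate 5 or 6 (median 0.782 each), NRAS-off replicate 5 (0.855) or MEK inhibitor replicate 4 (1.018), and also with no filter (0.782), median centring (0.752) or array weights (0.881).

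Glycolysis, hypoxia and cholesterol synthesis genes were lower in the NRAS-off arm. Of 17 glycolysis genes 12 were lower and none higher, or 13 when adjusted over the list alone (median −0.70, camera adjusted p = 8.54e-06, and adjusted p = 0.34 with an estimated correlation), with Slc2a1 at −1.31 ± 0.18 and Pgam1 at −0.94 ± 0.09. Of 24 hypoxia genes 16 were lower and 1 higher (median −0.53, camera adjusted p = 2.38e-05, and adjusted p = 0.358 with an estimated correlation), with Bnip3 at −1.45 ± 0.23 and Vegfa at −1.23 ± 0.08. Of 18 cholesterol synthesis genes 12 were lower and 1 higher (median −0.31, camera adjusted p = 0.00184, and adjusted p = 0.397 with an estimated correlation), with Sqle at −1.40 ± 0.15 and Idi1 at −1.19 ± 0.14. Of 21 lysosome and autophagy genes 14 were higher and 1 lower (median 0.30, camera adjusted p = 0.000306, and adjusted p = 0.308 with an estimated correlation), with Atp6v0d2 at 1.80 ± 0.27 and Ctsl at 0.54 ± 0.06.

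The genes furthest below the inhibitor arm without overlap were Crabp1, Nefl, Hmga2, Prkg2, Lgr6, Gzmd, Lbhd2, Dlk1, Pbk and Bub1, from −4.40 ± 0.22 for the retinoic acid binding protein gene Crabp1 to −2.94 ± 0.19 for Bub1. Those furthest above were Iigp1, Cd74, Calhm6, Clec7a, Cdkn1c, Cd52, H2-Aa, Fcgr3, Scrg1 and Cd48, from 3.37 ± 0.51 for the interferon-inducible GTPase gene Iigp1 to 2.84 ± 0.31 for Cd48. Adjusted over the list alone, 4 MAPK output genes, 2 cholesterol synthesis genes, 15 lysosome genes and 17 macrophage markers were higher. In all 3652 genes were higher in NRAS-off tumours and 3400 lower, with no overlap for 4227 of them. With macrophage and fibroblast scores as covariates 44 were higher and 146 lower, with a median SE 3.17 times as large, and the endothelial median turned to −0.16. The calls for MAPK output (−0.33), G1 regulators (−0.339), hypoxia (−0.028), glycolysis (−0.055), cholesterol synthesis (−0.355), dendritic (0.548), NK and lymphoid (0.624), mast cell (0.492) and adipocyte markers (0.404) ended, and the immediate early list passed (0.418).

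**Figure D3:**
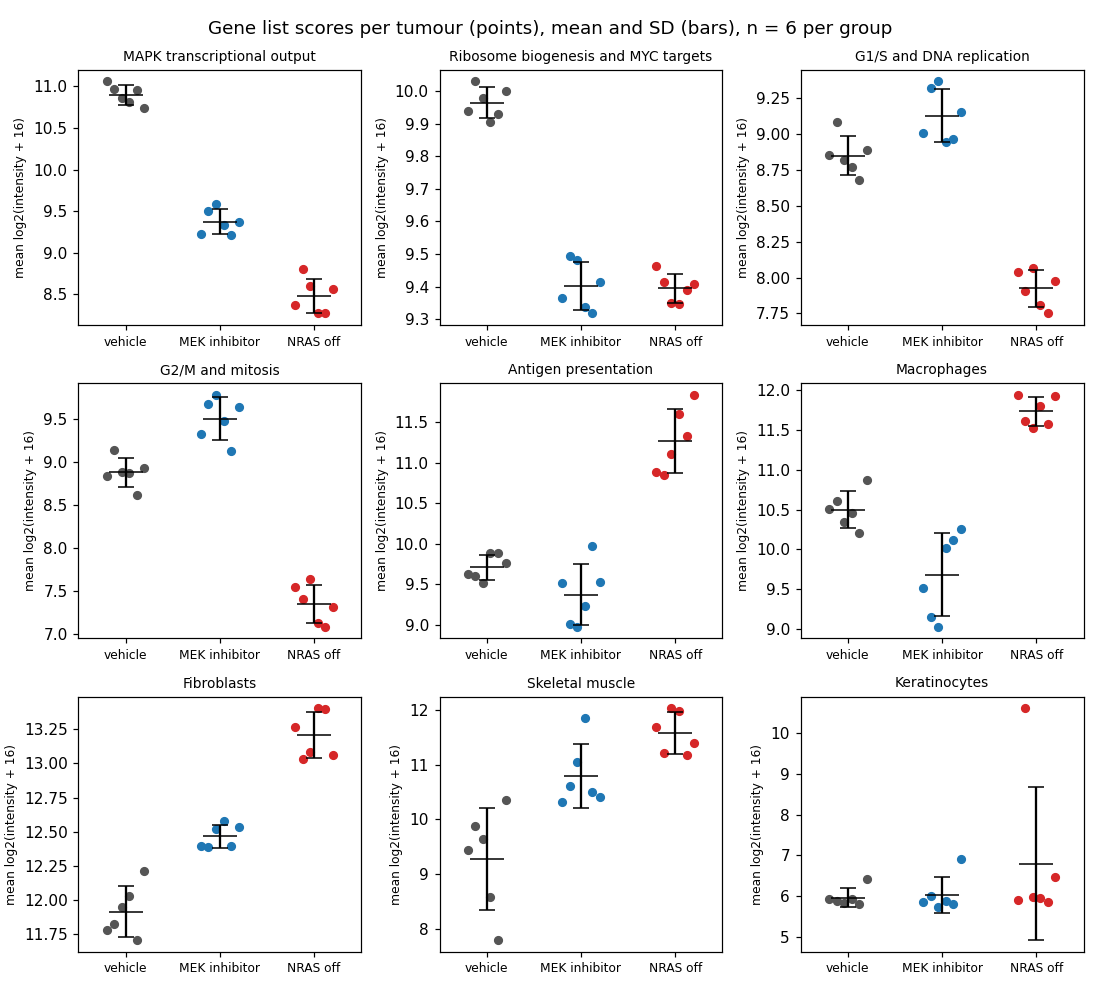
Mean log2(intensity + 16) over the tested members of 9 gene lists, for vehicle, MEK inhibitor and NRAS-off tumours. Points are single tumours, and bars show the mean and SD of 6. MAPK output falls in both treated arms, G2/M genes rise in MEK inhibitor and fall in NRAS-off tumours, and NRAS-off replicate 2 stands apart in the keratinocyte list.

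Comparing both arms with vehicle asks how much of the response is shared. In both arms 2393 genes rose and 2147 fell, against 1159.2 and 864.2 for independent lists of the same sizes. Simulated arms without any change gave 0, but hardly any gene can be called in such arms, so this 0 says nothing about the overlap. The shared fallers held Dusp6, Spry4, Etv4, Etv5, Fosl1, Ccnd1 and Myc, and the shared risers held Kcna1, Ptn, C1qtnf3, Bmf and Bcl2l11. Both contrasts use the same vehicle arrays, so the vehicle tumours were also split 3 against 3. Over the 20 splits, on average 1825.7 genes rose and 1730.6 fell in both arms, against 835.3 and 644.8 for independent lists. Across genes, which are not independent replicates, the changes in both arms correlated at r = 0.602, against 0.4999 in simulated unchanged arms and 0.571 on average (0.534 to 0.614) with split vehicle tumours. The covariance was 0.175 against 0.0059 simulated, a difference of 0.170.

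Genes also moved apart. In 2766 rising and 2344 falling genes the NRAS-off change passed both against vehicle and against the inhibitor arm in the same direction, and in 1197 rising and 1031 falling genes the inhibitor change did. Opposite changes against vehicle were found for 390 genes that fell in NRAS-off and rose in MEK inhibitor tumours and 346 genes that did the reverse, fewer than the 1002.5 and 999.2 of independent lists. The shared vehicle arrays could lower these counts, but with split vehicle tumours they were 288.9 and 243 on average, also fewer than the 731 and 738.9 of independent lists. The first group held 34 of the 35 G2/M genes and 18 of the 34 G1/S genes (Fisher's exact test, one-sided, adjusted p = 3.69e-52 and 5.39e-19, treating genes as independent), including Mki67, Top2a and Bub1. The second held 13 of 17 macrophage markers, 6 of 17 antigen presentation genes and 3 of 8 mast cell markers (adjusted p = 3.29e-17, 2.59e-05 and 0.00749), including Cd68, Mrc1, Cd74 and H2-Aa. With macrophage and fibroblast scores as covariates 1 gene of the first kind and none of the second passed, while the G2/M medians were −1.356 and 0.484. Members of both score lists were left out of these counts, so macrophage markers could not be among them. The scores lay 87.6% and 93.5% between the arms, and the median SE was 3.94 and 2.47 times as large against vehicle. These counts therefore do not show that the opposite changes came from host cells.

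Of 36 lists tested, 18 shifted in NRAS-off minus vehicle (10 up and 8 down), 13 in MEK inhibitor minus vehicle (6 up and 7 down) and 18 between the treated arms (11 up and 7 down). With an estimated correlation camera called 0 in each, with 5, 4 and 8 lists at an unadjusted p under 0.05, and fry, which tests whether a list moves one way on balance, called 32, 20 and 26. Among 100 splits of the tumours of each contrast, the actual one included, 13, 18 and 14 gave as many shifted lists, so chance is not excluded for these list counts, while 1 of 100 gave as many changed genes in each contrast. Splits with 1 or 2 tumours exchanged keep part of the arm difference, so not every split measures chance alone.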

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

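The tests of the keratinocyte pattern in this part were chosen after the result was seen. A tumour stood far from the other 5 of its arm, by the size of its gap relative to the range of the arm, in 37 of 657 groups of 6 tumours examined (9 of 108 list scores and 28 of 549 gene values). Chance gives about 1 in 20 such groups. The values below are log2 gaps to the nearest other tumour of the arm.

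Keratinocyte transcripts stood out in NRAS-off replicate 2, with a gap of 4.14 in the list score, 5.68 for Krt14 and 4.79 for Krt10. All 11 keratinocyte markers had their highest value of 18 tumours there. A mislabelled tumour of another arm is argued against by its MAPK list score of −0.79, below every MEK inhibitor (−0.37 to 0) and vehicle tumour (1.15 to 1.48), although above the other NRAS-off tumours (−1.31 to −0.99). Skin in the piece may account for the keratin values: in a second epidermal and hair follicle list 15 of 22 genes were highest in this tumour, between the bounds set for and against. Over these 22 genes the median gap to the highest other NRAS-off tumour was 2.04, and 7 had a gap of 3 or more. By the bounds set, skin in the piece stays open. No biological explanation was tested.

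In the same list MEK inhibitor replicate 6 was highest by 0.91 and vehicle replicate 6 by 0.47. Krt14 and Krt10 were highest in MEK inhibitor replicate 6 by 1.55 and 0.43. NRAS-off replicate 2 was also highest for immediate early genes by 0.33, for Slc2a1 by 0.66, for Sqle by 0.76 and for Ctsa by 0.11.

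Among the other list scores, p53 targets were highest in MEK inhibitor replicate 6 by 0.18. Neutrophil markers were lowest in vehicle replicate 5 by 0.38 and highest in MEK inhibitor replicate 2 by 0.41. Dendritic cell markers were highest in vehicle replicate 6 by 0.26, and NK and lymphoid markers in MEK inhibitor replicate 5 by 0.14.

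Among genes in vehicle tumours, replicate 2 was highest for Crabp1 by 0.62, Met by 0.74, Pbk by 0.31 and Plk2 by 0.51. Vehicle replicate 6 was lowest for Dusp4 by 0.37 and highest for Vwf by 0.73, and replicate 3 was lowest for H2-Aa by 0.5. Among NRAS-off tumours, replicate 1 was highest for Cldn5 by 0.54 and Nop58 by 0.28, and replicate 6 for Gzmb by 1.32 and Ifit2 by 0.38. NRAS-off replicate 4 was highest for Vwf by 0.34 and lowest for Ret by 0.25.

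Among MEK inhibitor tumours, replicate 1 was highest for Fmod by 1.32 and Foxo3 by 0.34 and lowest for Gzmd by 1.2. Replicate 4 was lowest for Bmp2 by 0.53. Replicate 5 was highest for Cdh19 by 0.3 and lowest for Mki67 by 0.44, Cs by 0.16 and Lbhd2 by 0.57.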

How the results depend on the processing

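The alternatives were fixed before the data were examined, except leaving out both tumours with the most keratinocyte transcript and the keratinocyte and muscle covariates, which were chosen after seeing the data. Leaving out each tumour in turn kept every count within 1.5 times: 4563 to 4836 genes rose and 3906 to 4188 fell in NRAS-off minus vehicle, 3351 to 3672 and 2967 to 3166 in MEK inhibitor minus vehicle, and 3443 to 3670 and 3135 to 3437 in NRAS-off minus MEK inhibitor. The correlation was 0.586 at its lowest. With the replicate block 4701 and 4027, 3614 and 3105, and 3609 and 3323 genes rose and fell, and 8612 of 8899, 6516 of 6787 and 6774 of 7052 calls were kept. The labels do not say whether a number marks shared tumours or days. A tumour's deviations matched its own number best in 1 of 6 for NRAS-off and vehicle, 4 of 6 for MEK inhibitor and vehicle and 2 of 6 for the treated arms, with mean correlations of 0.008, 0.097 and 0.098 against −0.002, −0.019 and −0.02 for other numbers. The block was left out from the start because the labels state no shared batch. Pairs with the same number exceeded 0.1 in 1, 4 and 3 of 6, so a partial sharing stays open, above all for MEK inhibitor and vehicle. With the most variable probe set per gene 8137 of 8868, 6047 of 6770 and 6239 of 7042 calls were kept and 168, 122 and 51 turned, and with the mean of all probe sets 7944 of 8815, 5843 of 6763 and 6251 of 7004 were kept and 38, 30 and 4 turned. None of the named values turned with these choices, median centring or quantile normalization. With the most variable and the mean probe set Braf passed in NRAS-off minus vehicle (0.275 and 0.13) and Cdkn1b in MEK inhibitor minus vehicle (−0.656 and −0.383), where Lpl ended with the first (0.357) and H2-Aa with the second (−0.544). Between the treated arms Myc ended with median centring (0.316) and quantile normalization (0.334), and Map2k1 passed with median centring (−0.18) and array weights (−0.168). Map2k1 ended in NRAS-off minus vehicle with quantile normalization (−0.13). Low signal limits the genes tested to 15005 of 18193.

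With a 2-fold threshold 942 rose and 633 fell, 278 and 314, and 674 and 412 in the 3 contrasts. Alike changes were 198 and 229, changes further by NRAS-off 482 and 283, further by MEK inhibitor 36 and 57, and opposite changes 3 and 15. At an adjusted p under 0.01 changes further by MEK inhibitor were 767 and 646 and opposite changes 227 and 186. These thresholds are stricter by construction.

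Camera with an estimated correlation called 0, 0 and 0 lists, with 5, 4 and 8 at an unadjusted p under 0.05, and fry called 32 and 20 in the contrasts against vehicle.

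With host cell covariates (macrophage and fibroblast scores) 157 and 283, 533 and 703, and 44 and 146 genes rose and fell. Alike changes were 108 and 183, further by NRAS-off 14 and 58, further by MEK inhibitor 11 and 8, opposite 1 and 0, the correlation 0.684, and 7 lists shifted between the treated arms. The scores lay 87.6% and 93.5% between the arms, and the median SE grew 3.94, 2.47 and 3.17 times. Genes that passed in both fits with opposite signs, as counted above for the probe set choices, were 13, 3 and 4 in the 3 contrasts. For the 511 gene values a turn is wider: the sign changed and the value passed in either fit. Many turned values therefore did not need to pass with the covariates. Of 511 gene values 176 stayed, 272 ended, 1 newly passed and 62 turned. Among the named ones, in NRAS-off minus vehicle these were Met 0.228, Vwf −0.212, Pvalb −0.103 and Map2k1 0.462; in MEK inhibitor minus vehicle Egfr −0.08, H2-Aa 0.256, Mmp9 0.425 and Cd68 0.139; and between the treated arms Cd48 −0.115, Mrc1 −0.914, Cpa3 −0.514, Fabp4 −0.308 and Pvalb −0.322. List medians that turned were, in NRAS-off minus vehicle, immediate early genes 0.515, hypoxia 0.281, glycolysis 0.065, endothelial −0.315, skeletal muscle −0.049 and Schwann cells −0.302; in MEK inhibitor minus vehicle, cytokines 0.383 and endothelial −0.277; and between the treated arms, endothelial −0.16. Cd68 and Mrc1 are members of the macrophage list, so the score holds them and part of their turn is built in. The 511 gene values include members of both score lists, while the gene counts leave them out. The cause was not tested.

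With keratinocyte and skeletal muscle covariates 2557 genes fell in NRAS-off minus vehicle, 1399 fell alike, 758 and 666 changed further by MEK inhibitor, 134 and 92 changed oppositely, and the correlation was 0.633. Of 511 gene values 450 stayed, 52 ended, 3 newly passed and 6 turned in the wider sense, with a pass in either fit. List calls ended in NRAS-off minus vehicle for hypoxia (−0.003), endothelial (0.267), dendritic (0.719), adipocyte (0.808) and Schwann cell markers (1.4), and in MEK inhibitor minus vehicle for G1/S (0.203) and Schwann cell markers (0.591). The muscle score lay 70.8% between the arms, and the cause was not tested.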

Other observations

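The tests of the G2/M and macrophage patterns were chosen after the results were seen, and the splits of the tumours before. The lists described next did not pass as a whole with the settings fixed at the start. Of 18 pigmentation genes 11 rose and 5 fell in NRAS-off minus vehicle (median 0.37, camera adjusted p = 0.177), with Rab27a, a melanosome transport GTPase gene, up by 1.75 ± 0.12. In MEK inhibitor minus vehicle 4 rose and 3 fell (median 0.12, adjusted p = 0.423), and between the treated arms 8 were higher and 5 lower (median 0.16, adjusted p = 0.322). Of 24 neural crest genes 13 rose and 9 fell in NRAS-off minus vehicle, where the median was 0.37 and the mean −0.054, with a test direction down (adjusted p = 0.929). Nes, which encodes nestin, fell by 2.42 ± 0.09 and Tfap2b fell by 2.63 ± 0.24. In MEK inhibitor minus vehicle 11 rose and 6 fell (median 0.15, adjusted p = 0.547), with Foxd3 up by 1.58 ± 0.08, and between the treated arms 5 were higher and 9 lower (median −0.13, adjusted p = 0.178). Of 22 receptor tyrosine kinase genes 8, 6 and 8 rose and 9, 6 and 7 fell in the 3 contrasts (adjusted p = 0.867, 0.806 and 0.867). Egfr and Ntrk2 rose by 1.79 ± 0.14 and 1.51 ± 0.15 in NRAS-off minus vehicle while Met fell by 1.42 ± 0.18, and Ret fell by 1.12 ± 0.18 under the inhibitor. The median of this list in NRAS-off minus vehicle was 0.025 with a mean of −0.007.

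Of 18 p53 targets 9, 6 and 8 rose and 6, 6 and 4 fell (adjusted p = 0.603, 0.929 and 0.544). Trp53inp1 rose by 1.45 ± 0.09 in NRAS-off and 1.22 ± 0.09 in MEK inhibitor tumours, and the inhibitor test pointed down with a median of 0.046. FOXO targets were 11 up and 5 down of 20 in NRAS-off minus vehicle (median 0.48, adjusted p = 0.0766, but passing with no filter at 0.478 and with macrophage and fibroblast covariates at 0.241), with Sesn3 and Fbxo32 up by 1.82 ± 0.08 and 1.68 ± 0.09, and 5 higher and 7 lower between the treated arms (adjusted p = 0.626). Of 15 WNT targets 5, 4 and 1 rose and 7, 3 and 4 fell (adjusted p = 0.385, 0.923 and 0.221), and Lef1 fell by 2.93 ± 0.11 in NRAS-off and fell by 1.57 ± 0.11 in MEK inhibitor tumours. The inhibitor median was 0.005 with a mean of −0.035. Of 24 matrix and protease genes 11, 8 and 7 rose and 6, 7 and 3 fell (adjusted p = 0.235, 0.806 and 0.221). Timp1 fell by 2.18 ± 0.13 and Plau rose by 2.10 ± 0.14 in NRAS-off minus vehicle, and the inhibitor median was 0.052 with a mean of −0.129. Of 25 oxidative phosphorylation genes 4, 0 and 4 rose and 9, 7 and 4 fell (adjusted p = 0.279, 0.106 and 0.969), and Cycs fell by 0.82 ± 0.07 in NRAS-off minus vehicle.

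Immediate early genes were 3 up and 7 down of 14 in NRAS-off minus vehicle (median −0.29, adjusted p = 0.433) and 4 higher and 3 lower between the treated arms (median 0.14, adjusted p = 0.531). The BCL2 family list in MEK inhibitor minus vehicle was 6 up and 4 down of 23 (median −0.007, mean 0.141, adjusted p = 0.514), and between the treated arms its mean was 0.056. Cytokines were 12 up and 3 down of 23 in NRAS-off minus vehicle (adjusted p = 0.174). Lysosome genes were 6 up and 7 down of 21 under the inhibitor (adjusted p = 0.683), and ATF4 and unfolded protein response genes were 5 higher and 9 lower of 22 between the treated arms (adjusted p = 0.546). Neutrophil markers were 4, 0 and 4 up and 0, 1 and 0 down of 9 (adjusted p = 0.288, 0.665 and 0.0805), and between the treated arms the list passed with the replicate block (median 0.348), with no filter (0.314) and without NRAS-off replicate 5 (0.356). Csf3r rose by 1.06 ± 0.14 in NRAS-off minus vehicle. Smooth muscle and pericyte markers were 5, 3 and 3 up and 2, 2 and 2 down of 10 (adjusted p = 0.867 in each contrast), with a median of 0.25 and a mean of −0.01 in NRAS-off minus vehicle, 0.069 and −0.146 between the treated arms. Cspg4 fell by 3.32 ± 0.10 in NRAS-off minus vehicle. Endothelial markers under the inhibitor had a median of 0.081 and a mean of −0.09. NK and lymphoid markers were 9 up and 2 down of 11 and mast cell markers 5 up and 1 down of 8 in NRAS-off minus vehicle (adjusted p = 0.178 and 0.416). Gzmb fell by 2.84 ± 0.36 and Mcpt1 fell by 2.69 ± 0.23. Under the inhibitor 1 of 11 NK and lymphoid markers fell (adjusted p = 0.546). Melanocytic markers were 4 higher and 3 lower of 9 between the treated arms (adjusted p = 0.576), and Schwann cell markers 3 higher of 5 (adjusted p = 0.315).

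G2/M genes fell in NRAS-off and rose in MEK inhibitor tumours. A lower share of tumour cells in NRAS-off with no other change in them would lower melanocytic transcripts too, and is argued against by a melanocytic list score higher by 0.56 than in vehicle tumours (8.942 ± 0.16 against 8.385 ± 0.105, SD, n = 6, exact permutation p = 0.00216, two-sided, the smallest of 924 splits). A lower share together with more melanocytic transcript per cell stays open. No biological explanation was tested.

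Macrophage markers rose in NRAS-off and fell in MEK inhibitor tumours. A lower share of tumour cells that raises every host cell type alike was examined with macrophage minus smooth muscle and pericyte scores. They were higher by 1.24 in NRAS-off than in vehicle tumours, and by 0.877 without Cspg4, which melanoma cells also make (exact permutation p = 0.00216 each, n = 6). The list still held Mcam, the melanoma cell adhesion molecule gene, so these differences do not decide it. Macrophage minus fibroblast scores differed by −0.056 (exact p = 0.647), so a joint rise of these cell types stays open. A fall of host cells as a whole under the inhibitor is argued against by a macrophage minus fibroblast difference of −1.37 (exact permutation p = 0.00216). For the rise in NRAS-off tumours, skin carried with replicate 2 is argued against by a macrophage median of 1.36 without both keratinocyte-rich tumours and 1.34 with all. MEK inhibitor replicate 6 does not enter this difference, so these medians do not address the fall under the inhibitor. In MEK inhibitor minus vehicle the macrophage call stayed without both tumours. Of 108 list results 107 stayed the same, and the 1 call that ended was that of Schwann cells. No biological explanation was tested.

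Among 100 splits of the 12 tumours of each contrast, the actual one included, 1 gave as many changed genes as the 8899 of NRAS-off minus vehicle, 1 as many as the 6787 of MEK inhibitor minus vehicle and 1 as many as the 7052 between the treated arms. The highest other splits gave 5832, 2920 and 4366, each with 1 tumour exchanged, which keeps part of the arm difference. Of the 99 other splits 88, 93 and 92 gave no changed gene. Counts as high as the actual ones were thus rare, at 1 in 100 of the splits drawn, which is the least this test can give. For shifted lists, 13, 18 and 14 of 100 splits gave as many as the actual 18, 13 and 18, with highest other counts of 21, 17 and 20, so chance is not excluded. Splits with no changed gene reached 21, 17 and 20 shifted lists, each with 2 tumours exchanged, so part of the arm difference stayed in them. With 3 tumours exchanged the highest counts were 13, 13 and 12. These lie below the actual counts in both contrasts with NRAS-off and equal the actual count in MEK inhibitor minus vehicle.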
